A study of Marchantia polymorpha with 12 samples.

How the data were processed

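Gene expression was measured by RNA sequencing in total seedlings of the liverwort Marchantia polymorpha, 14 days old, in wild type (the Cam1 ecotype, written WT) and in lines named pll1, pll2 and pll3. Each genotype had 3 libraries, which the labels describe as biological replicates, so that 12 libraries fell into 4 groups. The p-values of single genes measure the spread between these samples. Those of Fisher's exact test and of the permutation tests hold the calls fixed and treat genes, not samples, as the units. The camera tests of gene lists set the genes of a list against other genes. Libraries were made from poly(A) RNA with the TruSeq kit and sequenced on a HiSeq Xten instrument, per the labels' protocols. The submitters' processing notes name fastp and SAMtools 1.6. The aligner, the counting program, the genome build and the annotation release were not given in the sources used here.

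The deposited table of raw counts held whole-number counts per gene and library for 19472 genes, with exon coordinates and summed exon lengths, and its values had not been normalized by the authors. The deposited FPKM table gave the same genes scaled by exon length and by the library total. Each of its 233664 values was compared with count divided by exon length and column total, and the largest relative difference was 8.27e-09. The FPKM values therefore carried no correction beyond length and total. Whether counting used strand, and how reads with several equally good positions were treated, was not given in the sources used here. Values of members of multigene families (cupins, PR15, dirigent, peroxidase, polyphenol oxidase and LEA-like genes) and of overlapping gene models are uncertain for that reason.

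Library totals lay between 42283750 counts (pll3 replicate 1) and 45984858 counts (WT replicate 2). Levels are given in CPM, counts scaled to a TMM-corrected library total of 1e6. A floor of 3 counts corresponds to 0.0652 to 0.0709 CPM in single libraries, before that correction. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Where all 3 libraries of a group had 0 counts, a fold change is given as a lower bound against 3 counts summed over the group. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval.

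Symbols came from a reference table for the assembly MpTak2_v7.1, matched by the number in the identifier, and none of that table's coordinates were used. Of 18391 genes in the table, 17671 matched an identifier in the count table, and 99.96% of these lay on the same chromosome. The span of the gene agreed within 20% for 95.7% of the matches, against 17.9% after a shift by 1 gene. The table gave 3111 symbols, of which 2972 were kept and 2626 belonged to tested genes. Coordinates are those of the count table.

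Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 14715, libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 12 libraries. The common biological coefficient of variation was 0.130. A gene was called when its Benjamini-Hochberg adjusted p over all tested genes was under 0.05. All 6 pairs of genotypes were compared. Group values are given as mean CPM ± SD over 3 libraries, and log2 fold changes with their standard errors (SE). This SE was derived as the size of the log2 fold change divided by the square root of the F statistic. It is approximate for genes with few counts.

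The tests, groups, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Per mutant, the rule took the 12 named genes with the largest rise and the 12 with the largest fall among called genes whose 3 mutant libraries all lay on the same side of the 3 WT libraries, with a mean of at least 1 CPM in the higher group. It added 10 rising and 10 falling genes called in all 3 mutants, up to 4 members of each called list and up to 4 called genes of each sex chromosome. Unnamed genes appear by identifier, up to 2 each way, a rule that was written for data without names and was applied here beside it. The rule also asked for the PLL or CHD3-type genes themselves. The name table gave no gene under those names, so their level was not analysed here.

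Gene lists were defined by patterns applied to symbols and synonyms, since product descriptions were not used here. Of 28 lists, 21 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. The same test with an estimated correlation and fry were run beside it. After the data had been seen, 27 accidental symbol matches were removed from the lists, and 68 families of at least 8 genes sharing a symbol stem were defined and tested in the same way. Calls per chromosome were compared with Fisher's exact test, two-sided. Pairs of neighbouring genes called in the same direction were compared with 10000 permutations of the calls within chromosomes. Overlaps between mutants were set beside the overlap of independent lists and beside 20 simulations of unchanged groups against the same WT libraries.

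Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), a 2-fold minimum, each library left out in turn, the replicate number as a block, only the groups compared, and the sex chromosomes left out. Other divisions of the libraries were also tested. The leaving out of WT replicate 1 together with pll3 replicate 1, the exclusion of overlapping gene models, the permutation within expression level, the use of unedited lists and the leaving out of libraries for families and for lists between mutants were added after the data had been seen. Plots were drawn with matplotlib 3.10.9.

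Gene calls and list tests were tested on simulated data with the real library sizes and gene means of 14715 genes, and the chromosome and neighbour tests on gene sets drawn at random. The overlaps were not tested in this way. For the gene calls, 200 genes per mutant were changed. For pll1 against WT, 55.2% of 1.5-fold, 79.1% of 2-fold and 93.9% of 4-fold changes were recovered, with 3 false calls. For pll2 against WT the shares were 55.2%, 74.6% and 84.8%, with 4 false calls. For pll3 against WT they were 49.3%, 61.2% and 92.4%, also with 4 false calls. Each simulated gene had the same spread in all groups, and far fewer genes were changed than the 3941 to 5312 called against WT. The unequal spread of the real groups was not simulated, so these shares and false calls need not hold for the real data. A raised list was called in 20 of 20 simulated data sets, and 0 of 420 list tests without an effect were called by camera at the preset correlation. The simulated genes were drawn independently, so these list tests do not cover correlated members. In the real data the estimated correlation was 0.453 for histones. Of 40 random gene sets, 1 passed the neighbour test at 0.05. Of 720 chromosome tests on random sets, 3 were called, and an excess planted on chromosome 5 was called in 40 of 40 sets. The random sets were drawn without regard to neighbouring genes.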

Results

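RNA sequencing counts were collected from 14-day-old total seedlings of Marchantia polymorpha, a liverwort whose main plant body is haploid. Wild type of the Cam1 ecotype and the lines pll1, pll2 and pll3 were grown at 25 °C with 12 h of light, with 3 libraries per genotype. The series title places the work in a study of PKL, the CHD3-type chromatin remodeller of Arabidopsis, and the comparisons here ask how the transcriptome of each pll line differed from WT and from the other lines. The WT libraries held 43856917, 45984858 and 43611992 counts, the pll1 libraries 43868716, 45424832 and 44847540, the pll2 libraries 42521147, 45780433 and 44721988, and the pll3 libraries 42283750, 42928308 and 43977469. Between 15944 genes (pll3 replicate 1) and 16337 genes (pll2 replicate 2) had at least 1 count. The 10 most abundant genes took 3.38 to 5.10% of a library's counts, with the highest share in pll3 replicate 1, which also had the lowest TMM factor (0.947, against at most 1.02).

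Libraries lay closest to libraries of their own genotype. The correlation of log2 CPM across genes, which are not independent replicates, was 0.980 to 0.988 between WT libraries, 0.993 in pll1, 0.993 to 0.994 in pll2 and 0.983 to 0.993 in pll3. Between WT and mutant libraries it was 0.960 to 0.978 for pll1, 0.965 to 0.974 for pll2 and 0.949 to 0.968 for pll3. Principal component 1 held 36.7% of the variance and ordered the groups as pll1 (−47.7 to −38.0), WT (−25.0 to −2.49), pll2 (−0.86 to 5.22) and pll3 (47.4 to 67.1). Component 2 (21.2%) set WT apart at 32.4 to 54.0, and component 3 (18.5%) set pll2 apart at 40.3 to 47.7, with every other library between −20.6 and −11.5. No pair of replicates agreed within counting error. The chi-square per degree of freedom between replicates ran from 9.97 (pll2 replicates 2 and 3) to 103, and pll3 replicate 1 differed most from its partners (98.5 and 103).

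**Figure D1:**
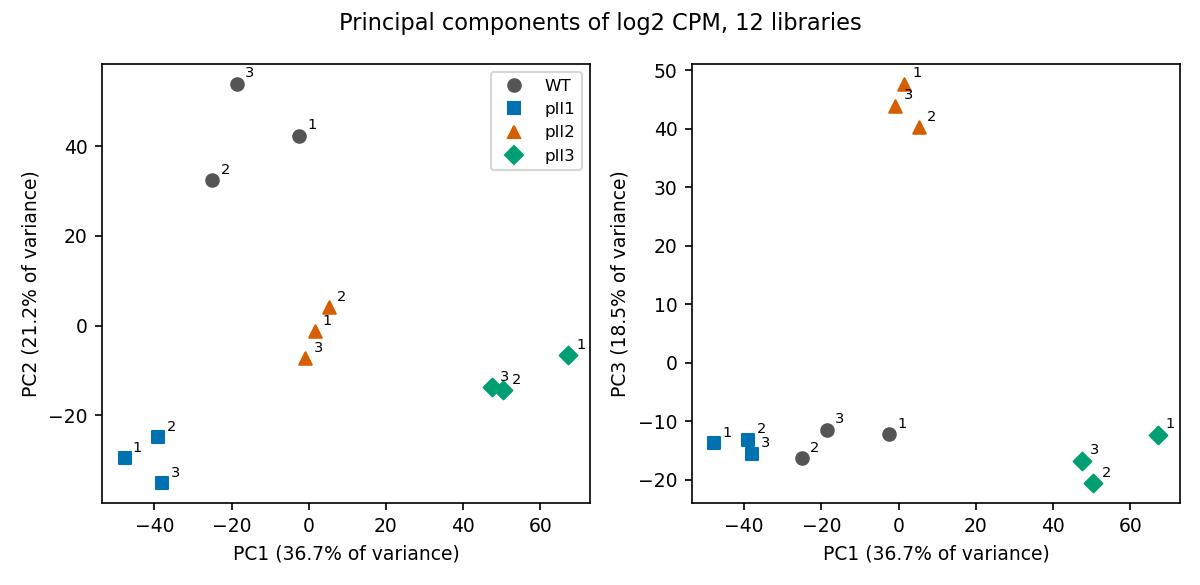
Position of each of the 12 libraries on principal components 1 and 2 and on components 1 and 3 of log2 CPM over 14715 genes, with the share of variance on each axis label, a symbol and colour per genotype and the replicate number beside each point. The 3 libraries of each genotype lie together, with pll3 at the highest and pll1 at the lowest values of component 1.

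The PLL genes carried no such name in the name table, so the lines were not checked by the level of the mutated gene, which was not analysed here. Of the chromatin remodeller list, only MpINO80 was tested, at 62.2 CPM in WT and 56.2, 58.9 and 56.0 CPM in pll1, pll2 and pll3. Its edgeR adjusted p was 0.052, 0.28 and 0.037, so that only the fall in pll3 passed the test. The 47 genes of chromosome U, carried by females, had 0 counts in every library, and chromosome V, carried by males, took 0.22 to 0.26% of the counts in each. Of 51 tested V genes, edgeR called 1 higher and 1 lower in pll1, 0 higher and 9 lower in pll2, and 1 higher and 10 lower in pll3. MpVg00980 lay at 140 CPM in WT, 114 CPM in pll2 (adjusted p = 0.00151) and 123 CPM in pll3 (adjusted p = 0.0133, edgeR). MpVg00350 fell from 38.5 CPM in WT to 31.7 CPM in pll2 and 30.4 CPM in pll3 (edgeR adjusted p = 0.0085 and 0.00221). The weakly expressed MpVg00085 fell from 0.64 CPM to 0.213 CPM in pll1 and 0.128 CPM in pll2 (edgeR adjusted p = 0.0118 and 0.00185), and MpVg00330 fell from 2.1 to 0.787 CPM in pll2 (edgeR adjusted p = 0.00207).

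In pll1, germin-type cupin genes and genes of pathogenesis-related protein classes led the named genes with the largest rises. MpCupin92, a germin-type cupin gene on chromosome 5 (25267392 to 25268021, 1 exon), rose 39.9-fold, from 0.0592 ± 0.0566 to 2.49 ± 1.15 CPM (SD, n = 3; log2 fold change 5.32, SE 0.70, edgeR adjusted p = 0.000535). MpCupin96 rose 17.2-fold and MpCupin88 17.1-fold, to 5.13 ± 0.942 and 2.34 ± 1.33 CPM. MpPR15j, from 0.548 ± 0.552 CPM, and MpPR15l, germin-like genes of the pathogenesis-related class PR15, rose 14.2-fold and 10.5-fold. MpPR9d, of the peroxidase class PR9, rose 11.3-fold to 1.88 ± 0.84 CPM, and MpLEA-like28 rose 10.3-fold to 3.71 ± 1.22 CPM. MpABCG29, an ABC transporter of the G class, rose 8.79-fold, the cytochrome P450 gene MpCYP829-like10 8.76-fold, and MpPR15f 8.71-fold to 17.0 ± 5.16 CPM. MpCAT1 rose 11.3-fold to 3.39 CPM, and MpCCC2, the most abundant of these genes, rose 8.53-fold to 39.4 ± 5.77 CPM (log2 fold change 3.09, SE 0.25, edgeR adjusted p = 3.46e-05). The highest edgeR adjusted p among the 12 was 0.00395 (MpCAT1). Without WT replicate 2 the rises were 72.3-fold (MpCupin96), 34.5-fold (MpPR15l), 28.8-fold (MpPR15j), 15.1-fold (MpCYP829-like10) and 14.2-fold (MpPR15f), and without WT replicate 1 that of MpCupin92 was 68.9-fold.

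The deepest named fall in pll1 was that of MpATXR6, named for a histone H3 lysine 27 monomethyltransferase of Arabidopsis, on chromosome 5 (22275970 to 22279583, 2 exons). It fell 42.7-fold, from 2.63 ± 0.858 to 0.0591 ± 0.0681 CPM (log2 fold change −5.42, SE 0.70, edgeR adjusted p = 0.000475). The pathogenesis-related gene MpPR1j fell 16.5-fold, MpPIP2-like, an aquaporin-type gene, 12.6-fold, and the class III peroxidase gene MpPOD113 10.3-fold, from 2.59 ± 0.742 to 0.249 ± 0.22 CPM. MpPPO40, a polyphenol oxidase gene, fell 9.36-fold from 22.1 ± 14.5 to 2.36 ± 1.53 CPM, and the wall-loosening expansin gene MpExpansin17 fell 9.17-fold. MpDIR28, a dirigent gene, fell 5.46-fold from 37.6 ± 9.44 to 6.88 ± 0.991 CPM (edgeR adjusted p = 1.9e-05). Falls of 5.33-fold (MpPPO11), 5.24-fold (MpPR1), 4.15-fold (MpGH16.30), 3.98-fold (MpPPO47) and 3.74-fold (MpPPO10) completed the 12, and the last pair had edgeR adjusted p of 0.0173 and 0.0129, which did not hold under every alternative. The fall of MpATXR6 was 106-fold without pll1 replicate 1, those of MpPOD113, MpPPO40 and MpExpansin17 were 20.6-fold, 14.9-fold and 14.7-fold without pll1 replicate 2, and that of MpPPO40 was 5.83-fold without WT replicate 3. Some unnamed genes went from none to clear expression or back. Mp4g14850 had 0 counts in WT and 5.37 ± 3.49 CPM in pll1, at least 240-fold higher (edgeR adjusted p = 0.000241). Mp5g20870 had 2 counts in WT and 6.5 ± 0.334 CPM in pll1, a ratio of 436 (95% counting interval 120 to 3604, edgeR adjusted p = 1.19e-05). Mp5g17070 and Mp1g03240 had 0 counts in pll1 against 2.12 ± 0.867 and 2.09 ± 0.748 CPM in WT, at least 95.6-fold and 94.9-fold lower (edgeR adjusted p = 0.00016 and 0.000759).

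Across the genome, edgeR called 3941 of 14715 genes (26.8%) in pll1 against WT, 2156 higher and 1785 lower. At least 2-fold changes were found in 951 of them, 638 higher and 313 lower. Without pll1 replicate 3 the count was 2199.

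Among the lists fixed beforehand, camera called 8 in pll1. Phenylpropanoid genes rose, with 13 of 17 members higher, 1 lower and 3 not called (13 higher and 3 lower when adjusted over the list alone). MpPAL10, a phenylalanine ammonia-lyase gene, rose from 207 ± 19.8 to 329 ± 30.3 CPM, Mp4CL1, of 4-coumarate ligase, from 32.8 to 60.5 CPM, MpCHIL1, of the chalcone isomerase-like class, from 19.9 to 30.1 CPM, and MpC4H2, of cinnamate hydroxylase, from 14.7 to 19.9 CPM. The list's camera adjusted p was 0.000217, and adjusted p = 0.122 with an estimated correlation. Of 62 disease and pathogenesis-related genes, 29 rose, 8 fell and 25 were not called (32 and 9 adjusted over the list alone), with MpPR9c at 26 ± 6.02 against 5.8 ± 1.63 CPM, MpPR15e at 22.4 against 5.85 CPM and MpPR1w at 11.8 ± 0.521 against 1.54 ± 1.09 CPM. This list had a camera adjusted p = 0.000168, and adjusted p = 0.561 with an estimated correlation. Of 80 late embryogenesis abundant and storage genes, 29 rose, 8 fell and 43 were not called (31 and 9 adjusted over the list alone). Cupins made up 65 of the 80 and other genes 15, so most of the 55 LEA-like genes, tested as a family further on, lay outside this list. In this list MpABI3A, named for a B3 factor of the abscisic acid response, rose from 37.7 ± 3.6 to 68.9 ± 4.61 CPM and MpCupin46 from 4.84 to 8.02 CPM, while MpCupin38 fell from 313 ± 68.9 to 168 ± 3.87 CPM. Its camera adjusted p was 0.000248, and adjusted p = 0.551 with an estimated correlation.

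Genes of terpene synthesis and of oil body cells, a cell type of the thallus that stores terpenoids, rose in pll1. Of 17 terpene genes, 9 rose, 2 fell and 6 were not called (10 and 2 adjusted over the list alone), and MpFTPSL3, a microbial-type terpene synthase-like gene, went from 16.9 ± 5.46 to 49.1 ± 9.41 CPM, MpFTPSL2 from 10.6 ± 0.572 to 20.7 ± 3.25 CPM, MpMTPSL5 from 4.98 to 9.7 CPM and MpTPS7 from 0.996 to 2.68 CPM. The camera adjusted p was 0.0419, and adjusted p = 0.551 with an estimated correlation. The terpene call was lost without pll1 replicate 1 (0.0595), pll3 replicate 1 (0.0577) or pll3 replicate 2 (0.0507). Of 16 oil body genes, 11 of them also in the terpene list, 10 rose, 1 fell (MpMTPSL1, from 39.5 to 30.6 CPM) and 5 were not called (11 and 1 adjusted over the list alone), at a camera adjusted p of 0.00102 and adjusted p = 0.551 with an estimated correlation. The histone list was called as lower, with 7 of 25 members lower, 1 higher and 17 not called (8 and 1 adjusted over the list alone). The linker histone gene MpH1 went from 190 ± 10.3 to 141 ± 7.78 CPM (log2 fold change −0.43, SE 0.06, edgeR adjusted p = 0.000485), MpH4a from 18.6 to 11.5 CPM, MpH2B.3 from 162 to 128 CPM and MpH4c from 23.9 to 18.5 CPM. The camera adjusted p of histones was 0.000437, and adjusted p = 0.561 with an estimated correlation. Of 16 cell cycle and replication genes, 5 fell, 0 rose and 11 were not called (the same numbers adjusted over the list alone). MpCYCD_2, of a D-type cyclin, went from 77.7 ± 5.49 to 55.2 ± 0.596 CPM, MpCDKB from 42.1 to 30.8 CPM, MpMCM6, of the replicative helicase, from 10.9 to 7.25 CPM, and MpCDKA from 59.5 to 52.0 CPM. This list had a camera adjusted p = 0.00554, and adjusted p = 0.561 with an estimated correlation. It was lost without WT replicate 1 (0.0861) and with fry (0.0573). Of 45 cell wall genes, 10 fell, 2 rose and 33 were not called (10 and 2 adjusted over the list alone). MpExpansin12 fell from 19.0 to 9.29 CPM and MpExpansin38 from 18.1 to 10.5 CPM, while MpExpansin36 rose from 2.27 to 5.44 CPM, at a camera adjusted p of 0.0133 and adjusted p = 0.551 with an estimated correlation.

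In pll2, a gene at the entry of phenylpropanoid synthesis rose together with germin-like, dirigent and proteinase inhibitor genes, while several peroxidase genes fell. MpPAL2, a phenylalanine ammonia-lyase gene on chromosome 4 (4096636 to 4099126, 1 exon), rose 11.9-fold from 12.2 ± 4.47 to 146 ± 31.5 CPM (SD, n = 3; log2 fold change 3.58, SE 0.37, edgeR adjusted p = 9.73e-05). The dirigent gene MpDIR29 rose 14.5-fold to 2.63 ± 0.271 CPM, MpPR15l 14.0-fold and MpPR15j 13.6-fold, the peroxidase gene MpPOD24 11.7-fold from 1.44 ± 0.172 to 16.8 ± 1.91 CPM (edgeR adjusted p = 8.14e-07), and the polyphenol oxidase gene MpPPO25 10.4-fold. MpPKS/CHS-like2, of the polyketide and chalcone synthase class, rose 10.2-fold to 5.31 ± 1.1 CPM. MpPR6c, of the proteinase inhibitor class PR6, was the most abundant of the 12 and rose 9.11-fold from 21.7 ± 15.4 to 198 ± 32.5 CPM. MpPR15h rose 8.79-fold to 35.2 ± 3.71 CPM, MpSQC1 9.97-fold to 24.9 ± 6.32 CPM, MpCYP704-like8 11.8-fold and MpCupin96 9.87-fold. The highest edgeR adjusted p among the 12 was that of MpCupin96 (0.00563). Without WT replicate 2 the rises were 45.7-fold (MpPR15l), 41.4-fold (MpCupin96), 27.6-fold (MpPR15j) and 14.5-fold (MpPR6c), and that of MpPPO25 was 20.5-fold without WT replicate 1.

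Peroxidase genes led the falls of named genes in pll2. MpPOD139 on chromosome 6 (14884918 to 14886824, 3 exons) fell 43.6-fold from 11.2 ± 6.43 to 0.253 ± 0.0965 CPM (log2 fold change −5.45, SE 0.65, edgeR adjusted p = 0.000199). MpPOD75 fell 30.3-fold, MpPOD113 21.1-fold, MpPOD153 10.6-fold, MpPOD55 9.98-fold to 1.23 ± 0.525 CPM and MpPOD57 8.13-fold. The dirigent gene MpDIR5 fell 10.9-fold from 112 ± 28.8 to 10.3 ± 3.07 CPM (edgeR adjusted p = 3.52e-05). Among cytochrome P450 genes, MpCYP707A, named for the abscisic acid 8'-hydroxylases, fell 7.86-fold from 19.5 ± 5.56 to 2.48 ± 0.342 CPM, MpCYP829-like11 8.17-fold, MpCYP829-like23 6.36-fold, MpCYP716AA1 12.5-fold (edgeR adjusted p = 0.0103) and MpCYP813B1 7.43-fold (edgeR adjusted p = 0.00897), which was 4.12-fold without WT replicate 3. Mp4g14850 was again detected, at 7.02 ± 0.943 CPM, at least 313-fold higher than in WT (edgeR adjusted p = 9.67e-05), and Mp8g19040 at 1.2 ± 0.57 CPM against 0 counts, at least 54.4-fold higher (edgeR adjusted p = 0.000749). Mp3g03850 had 0 counts in pll2 against 7.18 ± 5.52 CPM in WT, at least 318-fold lower (edgeR adjusted p = 0.0035). Mp5g17070 had 1 count, a ratio of 281 in favour of WT (95% counting interval 50.1 to 11140, edgeR adjusted p = 9.57e-05).

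edgeR called 4040 genes (27.5%) in pll2 against WT, 2092 higher and 1948 lower, and 971 changed at least 2-fold, 617 higher and 354 lower. Of the 21 lists, camera called the phenylpropanoid genes alone, of which 12 rose, 1 fell and 4 were not called (13 and 2 adjusted over the list alone). MpCHIL2 rose from 36.4 ± 3.28 to 74.5 ± 3.74 CPM (log2 fold change 1.03, SE 0.08, edgeR adjusted p = 1.65e-05), MpPAL4 from 33.8 ± 10.4 to 92.5 ± 15.6 CPM and MpPAL10 from 207 to 309 ± 8.7 CPM. The camera adjusted p was 0.000421, and adjusted p = 0.121 with an estimated correlation. The number of called lists was 4 without WT replicate 2 and 2 without WT replicate 3.

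In pll3, germin-type genes again led the rises of named genes, and several late embryogenesis abundant genes fell to near 0. MpCupin92 rose 108-fold to 6.78 ± 3.31 CPM (SD, n = 3; log2 fold change 6.76, SE 0.68, edgeR adjusted p = 3.95e-05), MpCupin88 44.4-fold to 6.08 ± 3.61 CPM, MpCupin96 39.4-fold to 11.8 ± 3.26 CPM, MpPR15j 27.4-fold to 15.3 ± 6.65 CPM and MpPR15l 23.8-fold. The ammonium transporter gene MpAMT2.1, on chromosome 2 (688353 to 691522, 4 exons), rose 40.1-fold from 0.106 ± 0.0952 to 4.32 ± 1.45 CPM (edgeR adjusted p = 0.000221). MpACOS21, an acyl-CoA synthetase gene on chromosome 1 (5299629 to 5300878, 1 exon), rose 34.6-fold from 1.24 ± 0.209 to 42.9 ± 6.33 CPM (log2 fold change 5.11, SE 0.20, edgeR adjusted p = 2.5e-07). The peroxidase genes MpPOD29, MpPR9d and MpPOD70 rose 19.4-fold, 18.8-fold and 16.7-fold, the polyphenol oxidase gene MpPPO23 16.1-fold to 19.4 ± 14.8 CPM, and the dirigent gene MpDIR65 15.3-fold to 12.1 ± 6.29 CPM. Without WT replicate 2 the rises were 165-fold (MpCupin96), 78.0-fold (MpPR15l), 55.4-fold (MpPR15j) and 26.6-fold (MpAMT2.1), without WT replicate 1 187-fold (MpCupin92) and 32.7-fold (MpPOD29), and without WT replicate 3 62.3-fold (MpAMT2.1). Without pll3 replicate 1 MpPOD70 rose 6.29-fold and MpPPO23 9.42-fold.

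Among the falls in pll3, MpLEA-like9 went from 7.82 ± 6.22 to 0.0474 ± 0.00219 CPM, a 156-fold fall (log2 fold change −7.28, SE 1.32, edgeR adjusted p = 0.00176). Late embryogenesis abundant proteins protect cells during drying. MpLEA-like60 fell 69.5-fold, MpLEAL7 62.4-fold from 14.4 ± 11.9 to 0.227 CPM, MpLEA-like53 39.8-fold, MpLEA-like61 31-fold and MpLEA1 18.8-fold from 12.2 ± 8.87 to 0.64 ± 0.286 CPM. The WT libraries were uneven in these genes, as their SD shows, and the 6 calls were lost in limma-voom. Without WT replicate 3 the falls were 43.5-fold (MpLEA-like60), 22.3-fold (MpLEA-like53) and 20.3-fold (MpLEA-like61), and that of MpLEA-like60 was 108-fold without pll3 replicate 2. MpDIR46 fell 17.0-fold from 155 ± 60.6 to 9.15 ± 3.97 CPM (edgeR adjusted p = 6.6e-05) and MpDIR48 15.0-fold from 106 ± 45.2 to 7.09 ± 4.05 CPM, while MpDIR62 was left with 2 counts (ratio of WT to pll3 76.5, 95% counting interval 20.8 to 637, edgeR adjusted p = 0.000272). MpATXR6 fell 23.4-fold to 0.108 ± 0.0961 CPM (edgeR adjusted p = 0.000298), or 35.4-fold without pll3 replicate 2, and MpPIP2-like 20.6-fold. MpCYP716AA1 had 0 counts in pll3 against 1.25 ± 0.859 CPM in WT, at least 53.2-fold lower (edgeR adjusted p = 0.00183). Mp4g14850 reached 8.11 ± 0.463 CPM, at least 363-fold higher than in WT (edgeR adjusted p = 4.95e-05), and Mp5g20870 reached 4.97 ± 1.03 CPM, a ratio of 334 (95% counting interval 92.2 to 2770, edgeR adjusted p = 5.34e-06). Mp4g15050 and Mp3g03850 had 0 counts in pll3 and were at least 610-fold and 303-fold lower than in WT (edgeR adjusted p = 0.00396 and 0.00272).

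edgeR called 5312 genes (36.1%) in pll3 against WT, 2785 higher and 2527 lower, and 1332 changed at least 2-fold, 804 higher and 528 lower. The majority of the calls turned when libraries were scaled by their totals alone (2450 higher, 2840 lower) and with limma on log2(FPKM + 0.1) (2431 and 2843) or log2(FPKM + 1) (2420 and 2813). When only the WT and pll3 libraries entered the model, the count was 3170.

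**Figure D2:**
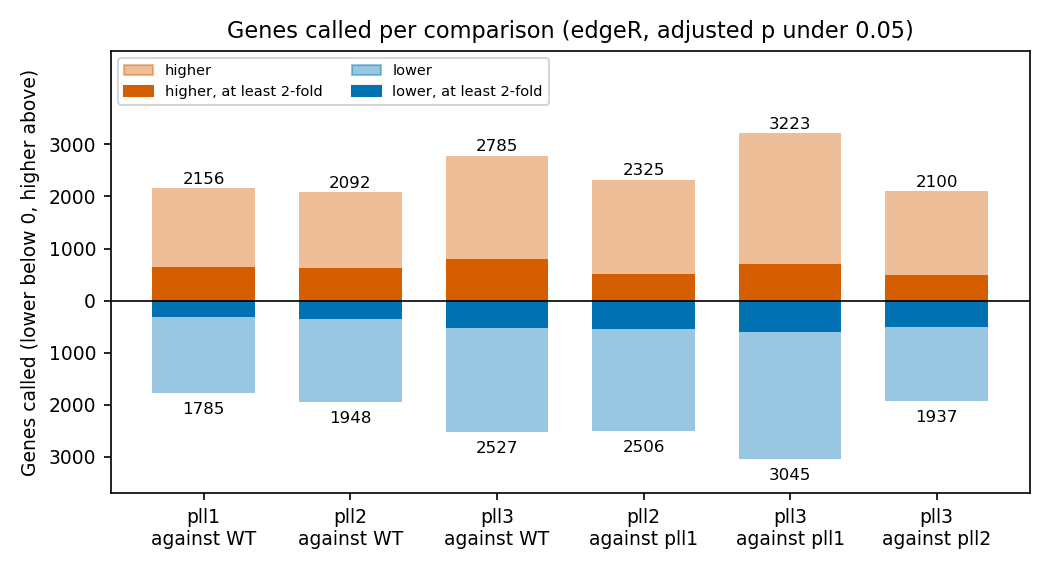
Number of genes called by edgeR (adjusted p under 0.05) in each of the 6 comparisons, with higher genes above 0 and lower genes below 0, and changes of at least 2-fold in the darker shade. The comparison of pll3 with pll1 has the most calls, 6268 in all.

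In pll3, camera called 5 lists, all raised. Of 183 peroxidase, laccase and polyphenol oxidase genes, 92 rose, 16 fell and 75 were not called (93 and 19 adjusted over the list alone). MpPOD25 went from 3.05 ± 0.483 to 26.6 ± 2.03 CPM (log2 fold change 3.12, SE 0.14, edgeR adjusted p = 2.73e-07), MpPOD22 from 4.93 to 39.7 ± 8.59 CPM, MpPOD24 from 1.44 to 17.8 CPM and MpPOD28 from 2.05 to 18.3 CPM. The list's camera adjusted p was 9.18e-08, and adjusted p = 0.0944 with an estimated correlation. Phenylpropanoid genes rose in 11 of 17 cases, with 1 lower and 5 not called (13 and 1 adjusted over the list alone). MpC4H2 rose from 14.7 to 29.6 CPM, MpPAL9 from 44.9 to 99.3 CPM and MpCHIL2 from 36.4 to 63.6 CPM, while the abundant MpPAL8 fell from 408 ± 37.1 to 130 ± 9.63 CPM (log2 fold change −1.65, SE 0.10, edgeR adjusted p = 1.38e-06). This list had a camera adjusted p = 0.000624, and adjusted p = 0.0944 with an estimated correlation. Disease and pathogenesis-related genes rose in 33 of 62 cases, with 8 lower and 21 not called (34 and 8 adjusted over the list alone), led by MpPR9c at 49.6 ± 5.77 CPM, MpPR15b at 42.8 ± 12.4 against 5.38 ± 1.07 CPM and MpPR15e at 40.5 ± 12 CPM. The camera adjusted p was 0.000294, and adjusted p = 0.577 with an estimated correlation. Cell wall genes rose in 20 of 45 cases, with 5 lower and 20 not called (20 and 6 adjusted over the list alone), among them MpExpansin36 from 2.27 to 12.1 ± 3.43 CPM, MpExpansin37 from 1.43 to 4.75 CPM, MpExpansin26 from 0.185 to 1.53 CPM and the receptor-like kinase gene MpRLK-Pelle_Extensin1 from 71.2 to 94.4 CPM, at a camera adjusted p of 0.0129 and adjusted p = 0.523 with an estimated correlation.

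The list of late embryogenesis abundant and storage genes was also raised in pll3, with 32 of 80 higher, 11 lower and 37 not called (35 and 13 adjusted over the list alone). The camera adjusted p was 0.00344, and adjusted p = 0.577 with an estimated correlation. It was 0.15 without WT replicate 1. The list, which leaves out most of the 55 LEA-like genes, was divided into cupins and other members after the data had been seen. Of 65 cupins, 29 rose and 4 fell in pll3 (median log2 fold change 0.70, camera adjusted p = 1.92e-05 over the 2 parts, and adjusted p = 0.102 with an estimated correlation), among them MpCupin37 from 1.31 ± 0.223 to 10.3 ± 4.22 CPM and MpCupin46 from 4.84 to 10.2 CPM. Of the other 15 members 3 rose, MpABI3A among them to 72.5 ± 7.37 CPM, and 7 fell (median −1.46, camera adjusted p = 0.234, not called). In pll1, 10 of these 15 were higher and 0 lower (median 1.82, camera adjusted p = 1.13e-06, and adjusted p = 0.118 with an estimated correlation), beside 19 higher and 8 lower cupins (median 0.33, camera adjusted p = 0.00547, and adjusted p = 0.188 with an estimated correlation). In pll2, 14 cupins rose and 3 fell (median 0.17), and of the other members 4 rose and 0 fell (median −0.04), with neither part called by camera (adjusted p = 0.0537 for each).

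**Figure D3:**
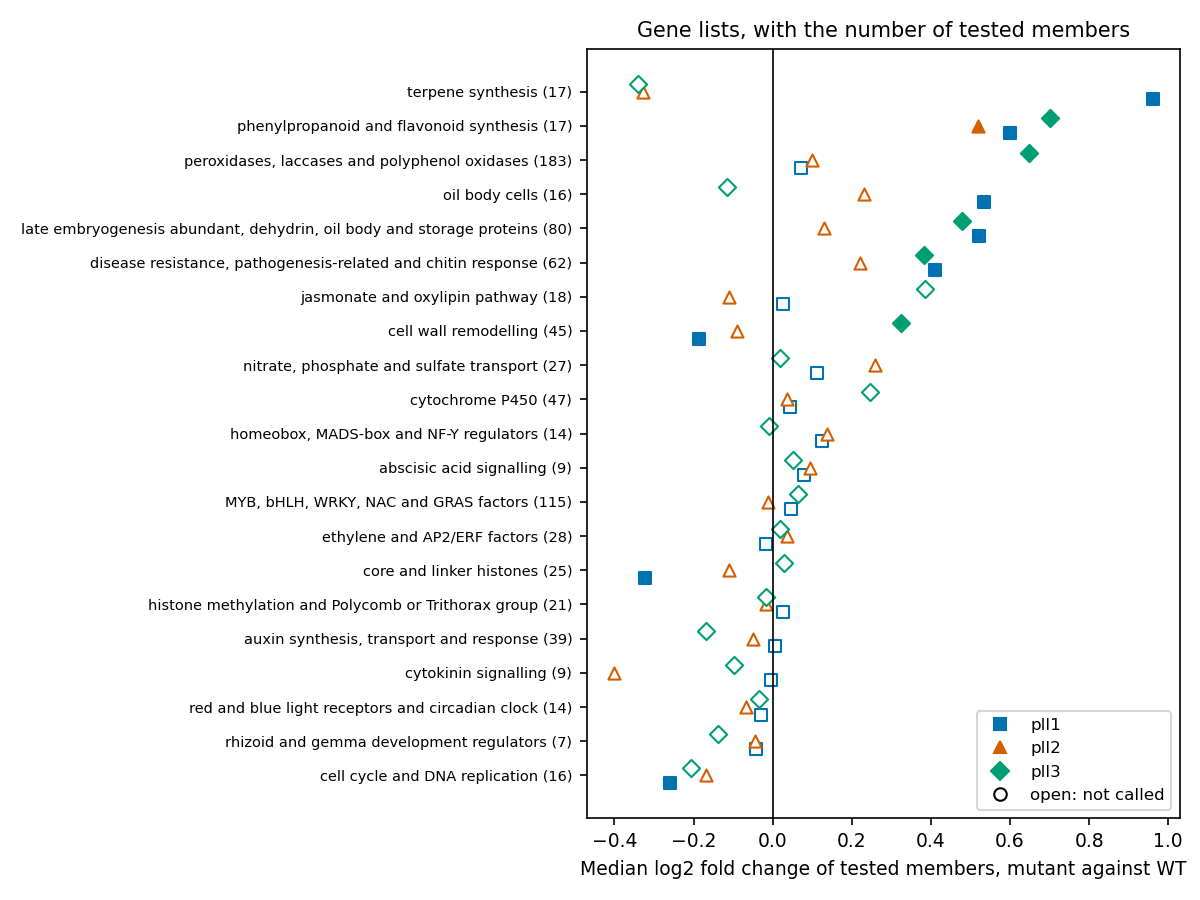
Median log2 fold change of the tested members of each of the 21 gene lists in pll1, pll2 and pll3 against WT, with filled symbols for lists called by camera at the preset correlation and open symbols for the others. The phenylpropanoid list has filled symbols above 0 in all 3 lines (medians 0.60, 0.52 and 0.70).

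With an estimated correlation, camera called 0, 0 and 0 of the 21 lists in pll1, pll2 and pll3 (1, 1 and 2 at an unadjusted p under 0.05), while fry, which does not set a list against other genes, called 8, 4 and 9. At the preset correlation, camera called the phenylpropanoid list in all 3 lines and the storage, disease-related and cell wall lists in pll1 and pll3, the last in opposite directions. The other lists were called in at most 1 line, and differences between lines were tested separately as given further on. In each line, a division of the libraries that mixed genotypes called more lists than the real one, as also given further on. In pll2 the adjusted p by camera was 0.234 for histones, 0.156 for late embryogenesis abundant and storage genes (18 higher, 3 lower), 0.85 for terpene synthesis, 0.454 for peroxidases and related oxidases (43 higher, 42 lower), 0.49 for the cell wall, 0.234 for the cell cycle, 0.275 for oil body cells and 0.156 for disease-related genes (23 higher, 9 lower). In pll1 the oxidases had a camera adjusted p of 0.372 (44 higher, 25 lower). In pll3 the camera adjusted p was 0.991 for histones, 0.539 for terpene synthesis, 0.358 for the cell cycle and 0.625 for oil body cells. Histone methylation and Polycomb or Trithorax genes, the list closest to chromatin regulation, were called in no line (camera adjusted p = 0.681, 0.49 and 0.539), with 0, 1 and 0 of 21 higher and 3, 4 and 4 lower. Further lists called by camera in no line were, with adjusted p in pll1, pll2 and pll3, abscisic acid signalling (0.294, 0.451 and 0.991), auxin (0.807, 0.451 and 0.327), cytokinin (0.53, 0.234 and 0.438), jasmonate (0.807, 0.85 and 0.401) and ethylene and AP2 factors (0.681, 0.794 and 0.794). The same held by camera for cytochrome P450 genes (0.372, 0.49 and 0.264), rhizoid and gemma regulators (0.355, 0.874 and 0.755), homeobox, MADS-box and NF-Y factors (0.93, 0.608 and 0.989) and the MYB, bHLH, WRKY, NAC and GRAS factors (0.294, 0.997 and 0.625). Nitrate, phosphate and sulfate transport (0.197, 0.156 and 0.834) and light receptors with the circadian clock (0.681, 0.451 and 0.539) were likewise not called by camera. Of the 14 called list tests, 0 had a median, mean and test of differing sign, against 11 of the 49 not called. Lists with under 5 tested members were not tested. They were chromatin remodellers, photosystem, carbon fixation, ribosomal and heat shock proteins, sperm and transposon-derived genes. Among their members MpRBCS, of the small subunit of Rubisco, stood at 146 CPM in pll1 against 244 CPM in WT (log2 fold change −0.74, SE 0.19, edgeR adjusted p = 0.015), and the heat shock factor gene MpHSF1 rose in pll3 (log2 fold change 0.37, edgeR adjusted p = 0.017).

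Germin-like, proteinase inhibitor and dirigent genes were among those that rose in all 3 lines. In total 992 genes were called by edgeR with the same sign in all 3, of which 630 were higher and 362 lower, and 224 of them (169 higher, 55 lower) changed at least 2-fold each time. MpPR15j (chromosome 6, 22831474 to 22832094), MpPR15l (22839255 to 22840427) and MpCupin96 (22846546 to 22847166) lie close together and rose by log2 fold changes of 3.83, 3.77 and 4.78 (MpPR15j), 3.40, 3.8 and 4.57 (MpPR15l) and 4.10, 3.3 and 5.30 (MpCupin96) in pll1, pll2 and pll3. On chromosome 5, MpPR15f (25223015 to 25223656) and MpCupin88 (25231112 to 25231741) form another such group, with log2 fold changes of 3.12, 2.49 and 3.87 and of 4.10, 3.07 and 5.47. MpPR6c went from 21.7 ± 15.4 CPM in WT to 144 ± 40.2, 198 ± 32.5 and 158 ± 25.3 CPM. MpDIR29 rose by 3.07, 3.86 and 3.60, MpPPO25 by 3.01, 3.37 and 3.1, MpPKS/CHS-like2 by 2.84, 3.35 and 2.92, and MpABCG29 by 3.14, 2.31 and 3.25. Among the falling genes, MpPOD113 had log2 fold changes of −3.36, −4.40 and −3.22, MpPIP2-like of −3.65, −2.49 and −4.37, and MpPR1j of −4.05, −2.27 and −1.69. MpKAI2B, named for the receptors of karrikins, lay at 19.6 ± 3.41 CPM in WT and at 6.16 ± 1.37, 5.8 ± 0.208 and 8.03 ± 2.88 CPM in the mutants. MpCYP707A fell from 19.5 to 7.19, 2.48 and 3.5 CPM, and MpGDPD, of the glycerophosphodiester phosphodiesterases, from 198 ± 84.8 to 71.5, 54.9 and 72.9 CPM. MpGH16.30, a glycoside hydrolase gene, had −2.05, −1.51 and −1.49, MpCYP829-like11 −1.30, −3.03 and −2.37, MpDIR28 −2.45, −1.30 and −1.99, and MpATXR6 −5.42, −1.44 and −4.55. Without WT replicate 1 the log2 fold changes of MpPPO25 were 4, 4.36 and 4.09, without WT replicate 2 those of MpPR15f were 3.83, 3.2 and 4.58, and without pll2 replicate 2 those in pll2 were −3.66 for MpPIP2-like and −3.44 for MpPR1j. The edgeR adjusted p nearest to the threshold were 0.0473 for MpATXR6 in pll2 and 0.0273 for MpPR1j in pll3.

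**Figure D4:**
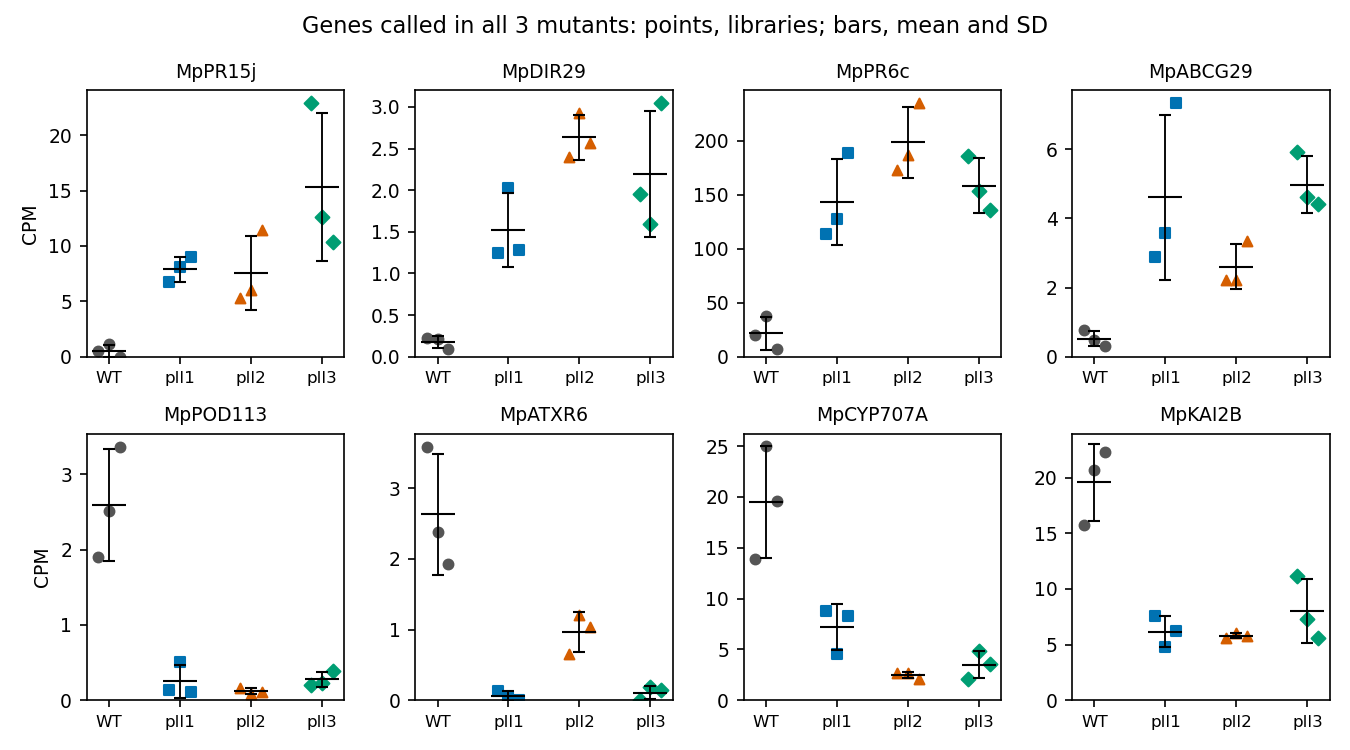
Level in CPM, on a separate linear axis for each gene, of 8 genes called with the same sign in all 3 mutants, with a point per library, a colour per genotype and bars for mean and SD (n = 3). For each gene the mutant libraries lie on the same side of the 3 WT libraries, as the rule for naming genes required.

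The unnamed Mp4g14850 (chromosome 4, 17117646 to 17125775, 6 exons) was the most extreme shared rise. Mp4g16980 had 2 counts in WT and 1.34, 1.77 and 1.02 CPM in pll1, pll2 and pll3, with ratios of 89.8 (95% counting interval 24.5 to 747), 118 (32.4 to 982) and 69.3 (18.8 to 579). Mp3g03850 was also 153-fold lower in pll1, at 0.0442 CPM (edgeR adjusted p = 0.00589), or 98.6-fold without WT replicate 3 and 288-fold without pll1 replicate 1. Mp5g17070 (chromosome 5, 18098623 to 18099880, 2 exons), the neighbour of MpPOD113 (18104044 to 18106254), kept 2 counts in pll3, a ratio of WT to pll3 of 134 (36.7 to 1109).

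Same-sign calls were shared more often than independent lists would share them. pll1 and pll2 had 1452 calls of the same sign in common (880 higher, 572 lower) where independent lists would share 543, pll1 and pll3 had 1602 (1002 and 600) against 715, and pll2 and pll3 had 2252 (1210 and 1042) against 730. Calls common to all 3 lines numbered 992 against 98.6. Opposite signs were found for 194, 315 and 161 genes, and these numbers depended on single libraries. For pll1 and pll2 there were 123 and 112 without WT replicate 1 or 3, 112, 120 and 91 without pll1 replicate 1, 2 or 3, 111 and 116 without pll2 replicate 1 or 3, and 354 without pll3 replicate 1. For pll1 and pll3 there were 168 and 170 without WT replicate 2 or 3 and 149, 191 and 141 without pll1 replicate 1, 2 or 3, and for pll2 and pll3 there were 95 without WT replicate 2 and 103 and 96 without pll2 replicate 1 or 3. Against the same WT libraries, 20 simulations of unchanged groups gave 0 shared calls by edgeR, a value for groups without effects that says nothing of the overlap to be expected between long lists with shared controls. The correlation of log2 fold changes across genes was 0.46, 0.31 and 0.51, where the simulations gave 0.50 for each pair from the shared controls alone. The covariance was 0.212, 0.182 and 0.292, against 0.0311 simulated, which leaves differences of 0.181, 0.151 and 0.261. The 3 WT libraries could not be split into groups of at least 2, so part of the excess of shared calls may come from the shared controls.

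Between the mutants, oxidase and cell wall genes were higher and oil body genes, markers of another cell type, lower in pll3 than in pll1 and pll2. edgeR called 4831 genes between pll2 and pll1 (2325 higher and 2506 lower in pll2, 1059 at least 2-fold), 6268 between pll3 and pll1 (3223 higher and 3045 lower in pll3, 1304 at least 2-fold) and 4037 between pll3 and pll2 (2100 and 1937, 993 at least 2-fold). With library totals alone the majority turned to lower calls for pll3 against pll1 (2764 higher, 3492 lower) and against pll2 (1837 and 2161). The count for pll2 against pll1 was 3094 without pll2 replicate 1 and 3216 without pll1 replicate 3. Of 183 oxidase genes, 92 were higher and 16 lower in pll3 than in pll1 (camera adjusted p = 7.95e-06, and adjusted p = 0.145 with an estimated correlation), and 84 higher and 9 lower than in pll2 (camera adjusted p = 1.7e-09, and adjusted p = 0.0809 with an estimated correlation). Cell wall genes were higher in pll3 than in pll1 in 28 cases and lower in 2 (camera adjusted p = 2.24e-05, and adjusted p = 0.145 with an estimated correlation). Against pll2 they were higher in 20 and lower in 2 (camera adjusted p = 0.000103, and adjusted p = 0.164 with an estimated correlation). Of the 16 oil body genes, 2 were higher and 9 lower in pll3 than in pll1 (camera adjusted p = 0.0171, and adjusted p = 0.643 with an estimated correlation), and 2 higher and 8 lower than in pll2 (camera adjusted p = 0.0225, and adjusted p = 0.768 with an estimated correlation). The latter call was lost without WT replicate 2 (0.0538), pll3 replicate 1 (0.0531) or pll3 replicate 2 (0.0613). Between pll2 and pll1 camera called 0 lists (2 at an unadjusted p under 0.05, and 0 by fry), and the lowest adjusted p by camera was 0.357.

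Called genes were unevenly spread over the chromosomes. Fisher's test takes genes as independent, while called genes lay next to one another more often than permuted calls, so its p-values may be too small. On chromosome 5, with 1816 tested genes, 18.1% were higher in pll1 against 14.2% elsewhere (odds ratio 1.33, Fisher's exact test, adjusted p = 0.000477), 16.9% in pll2 against 13.8% (odds ratio 1.27, exact adjusted p = 0.00613) and 24.7% in pll3 against 18.1% (odds ratio 1.48, exact adjusted p = 5.00e-09). On chromosome 1, 12.2% of 2463 genes were higher in pll1 against 15.1% elsewhere (odds ratio 0.777, exact adjusted p = 0.00218), and 16.5% in pll3 against 19.4% (odds ratio 0.822, exact adjusted p = 0.00649). Of 51 V genes, 1, 0 and 1 were higher in pll1, pll2 and pll3 (Fisher's exact test on edgeR calls, adjusted p = 0.0328, 0.00649 and 0.00613), while 1, 9 and 10 were lower (2.0, 17.6 and 19.6%, against 12.2, 13.2 and 17.2% elsewhere, exact adjusted p = 0.0788, 0.716 and 0.747). The call of chromosome 5 in pll2 and that of chromosome 1 in pll3 were both lost without WT replicate 1 (0.0788 each), and those of chromosome V with a 2-fold minimum. The V call in pll1 was also lost without WT replicate 2 (0.0522), pll1 replicate 2 (0.119) or 3 (0.337), pll2 replicate 2 (0.0517) or 3 (0.0519), or pll3 replicate 3 (0.134), and that in pll3 without pll3 replicate 3 (0.0553).

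Genes called in the same direction lay next to one another more often than permuted calls. Of 14645 adjacent pairs, 537 were both higher in pll1 against 320.9 on average after permutation (1.67 times), 511 in pll2 against 299.5 (1.71 times) and 805 in pll3 against 534.1 (1.51 times). Pairs of lower genes numbered 322 against 217.1 (1.48 times), 376 against 255.1 (1.47 times) and 606 against 431.7 (1.40 times). Each permutation test gave 1e-04, the smallest p that 10000 permutations can give. For changes of at least 2-fold the ratios were 4.20 to 6.39. The numbers of pairs depended on single libraries, while without any 1 library the ratios stayed between 1.36 and 1.99. In pll1 the pairs of higher genes numbered 330 without WT replicate 3 and 345 and 274 without pll1 replicate 1 or 3, and those of lower genes 131 without WT replicate 3, 112, 152 and 74 without pll1 replicate 1, 2 or 3 and 548 without pll3 replicate 1. In pll2 the pairs of higher genes numbered 301 without pll2 replicate 3, and those of lower genes 208 without WT replicate 2 and 177, 243 and 187 without pll2 replicate 1, 2 or 3.

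The balance of rises and falls varied with expression level. In the lowest of 4 equal bins of mean level (0.105 to 4.79 CPM), 60.3% of the calls in pll1, 61.2% in pll2 and 54.2% in pll3 were higher, in the second bin 52.4%, 51.8% and 63.4%, in the third 55.1%, 47.6% and 49.9%, and in the highest bin (63.9 to 6320 CPM) 53.1%, 49.4% and 45.0%. The shares did not fall evenly with level, and that of pll3 was highest in the second bin. Changes of at least 2-fold were concentrated in the lowest bin, with 346 higher and 205 lower in pll1, 360 and 198 in pll2 and 422 and 360 in pll3, against 48 and 15, 33 and 23, and 68 and 22 in the highest.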

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

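Of the tests in this part, the correlation tests for a wrong label of WT replicate 1 and of WT replicate 3, the test of isolated LEA-like genes, the test of pll3 for MpBHLH20, the test of divergent neighbours, the lists between mutants without single libraries and the tests without overlapping gene models and without neighbours of the same name were chosen only after the result was seen.

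Differences between the mutants themselves passed 8 list tests, which cover 5 different lists, and a test for many single genes. Against pll1, pll3 had higher levels of peroxidase, laccase and polyphenol oxidase genes (camera adjusted p = 7.95e-06), cell wall genes (2.24e-05) and histone genes (0.0146, with 13 of 25 higher and 2 lower), and lower levels of oil body genes (0.0171, with 2 of 16 higher and 9 lower). Against pll2, pll3 had higher oxidase genes (camera adjusted p = 1.7e-09), cell wall genes (0.000103) and disease-related genes (0.0112, with 18 higher and 5 lower), and lower oil body genes (0.0225, with 2 higher and 8 lower). None of these 8 passed with an estimated correlation, where the histone list had an adjusted p of 0.911, the oil body list 0.643 and 0.768, and the disease-related list 0.768 by camera. The histone call was lost without pll1 replicate 3 (0.0641), the oil body call against pll2 without WT replicate 2 (0.0538), pll3 replicate 1 (0.0531) or 2 (0.0613), and the disease-related call without pll3 replicate 2 (0.0613) or 3 (0.0524), by camera. Genes called by edgeR in opposite directions against WT and called between the mutants numbered 194 for pll1 and pll2, 315 for pll1 and pll3 and 161 for pll2 and pll3. These numbers were the same without the second condition, so the calls between the mutants add no support for these genes. Genes of opposite sign numbered 91 and 141 for the first 2 pairs without pll1 replicate 3, 354 for the first without pll3 replicate 1, and 95 for the last without WT replicate 2. MpGH3.5, of the enzymes that conjugate hormones to amino acids, lay at 11.5 CPM in WT, 4.01 CPM in pll1 and 75.4 CPM in pll2. MpCALEOSIN, a caleosin gene, lay at 0.516 CPM in WT, 4.25 CPM in pll1 and 0.032 CPM in pll3. MpRLK-Pelle_L-LEC13, a receptor-like kinase gene, lay at 0.516 CPM in WT, 0.0885 CPM in pll1, 0.122 CPM in pll2 and 3.46 CPM in pll3, and MpPPO26 at 0.287 CPM in WT, 1.75 CPM in pll1 and 0.023 CPM in pll2.

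LEA-like genes lay higher in pll1 than in pll3 on the median and were uneven in WT. The median deviation of the 55 genes from their mean log2 level was 1, 0.71 and 0.53 in the pll1 libraries, −1.36, −0.31 and −0.48 in the pll3 libraries and −1.14, −0.02 and 0.03 in the WT libraries, and MpLEA-like9 had 0.632, 11.6 and 11.2 CPM in WT. A wrong label of WT replicate 1 is argued against, since its correlation across genes with another WT library (0.9851) was above that with any mutant library (0.9744). Reads shared between near-identical copies cannot be told apart from a common change, because the 31 members with no other LEA-like gene within 5 places differed between pll3 and pll1 by a median of −0.52 with an interquartile range of −1.94 to 0.11. Seedling pools that differed in stage or tissue apart from genotype also cannot be told apart from an effect of genotype, since WT replicate 1 deviated from the other WT libraries along the difference between pll3 and pll1 with r = 0.218 (SE 0.04, 14660 genes outside the family), between the bounds of 0.1 and 0.3 set beforehand. The SE of r, here and for MpBHLH20 below, comes from leaving out each numbered chromosome in turn. It measures spread between chromosomes, not between seedling pools.

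MpBHLH20 (synonym MpBNB), of the regulators of reproductive organs and germ cells, was present in pll1 (3.34, 2.45 and 1.82 CPM) and in WT replicates 1 and 2 (4.20 and 1.51 CPM), and near or at 0 in WT replicate 3 (0), pll2 (0.141, 0.0438 and 0.2 CPM) and pll3 (0.05, 0 and 0 CPM). The unnamed Mp4g05770 had the same distribution at a far higher level, with 958, 320 and 2.04 CPM in WT, 1530, 1290 and 659 CPM in pll1, 22.5, 16.4 and 18.1 CPM in pll2 and 2.65, 2.81 and 6.61 CPM in pll3. A wrong label of WT replicate 3 is argued against, since its correlation with another WT library (0.9882) was above that with any mutant library (0.9703). Pools of seedlings that differed in stage cannot be told apart from an effect of genotype in pll3, since along the difference between pll3 and pll1 WT replicate 3 deviated with r = −0.021 (SE 0.035), but WT replicates 1 and 2, which hold the transcript, with r = 0.269 and −0.33. For pll2 such pools also stay open. Along the difference between pll2 and pll1, r of WT replicate 3 was 0.085 (SE 0.013), under the bound of 0.1 but within 2 SE of it. That SE was computed after r had been seen. WT replicates 1 and 2 deviated along the same difference with r = 0.167 and −0.327. A difference limited to few reproductive genes in both lines stays open too.

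Called genes lay next to one another more often than permuted calls. Overlapping gene models are argued against as the whole cause, since without overlapping pairs the lowest of the 6 ratios was 1.35. Reads running on into the next gene are argued against as the whole cause by the 3355 divergent pairs, with a lowest ratio of 1.5. Their 5' ends face each other, so that neither runs into the other. Over the 7224 same-strand pairs the ratios in pll1, pll2 and pll3 were 1.80, 1.76 and 1.58 for higher genes and 1.31, 1.49 and 1.37 for lower genes. A share of such reads in those pairs stays open. Over the 3296 convergent pairs the ratios were 1.11 to 1.33. Those of lower genes in pll2 (1.13, permutation p = 0.159) and pll3 (1.11, p = 0.127) did not pass the test. Tandem copies cannot be told apart from a regional effect, since only 2626 of 14715 tested genes carried a symbol and the lowest ratio of 1.39 without neighbours of the same name still holds unnamed copies. Neighbours that vary together for other reasons remain a candidate explanation, since deviations from the group means, which hold no genotype effect, correlated at 0.099 between adjacent genes and at 0.004 between genes 50 places apart, a difference of 0.096, and regional chromatin effects of the mutations were not tested apart from this.

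For each of the 6 pairs of genotypes, 1 of the 10 divisions of the 6 libraries, the real one, gave as many called genes, and 10 divisions are too few for a share under 0.05. The real counts by edgeR were 3941, 4040, 5312, 4831, 6268 and 4037, and the highest of the others were 0, 0, 1, 0, 0 and 0. For the lists, 3 of 10 divisions in pll1, 8 of 10 in pll2 and 6 of 10 in pll3, the real one included, gave as many calls by camera (real 8, 1 and 5, highest other 9, 9 and 7). In each line a division that mixed genotypes thus called more lists than the real one. The number of called lists therefore did not set the real division apart from others. In 100 divisions of the 12 libraries, the real one alone gave a value as large for each of the following. They were the genes common to 3 mutants (992, highest other 488) and the overlaps of pll1 with pll2 (1452, highest other 593), pll1 with pll3 (1602, 514) and pll2 with pll3 (2252, 699). The chromosome calls (8, highest other 3) and the excess of neighbouring pairs (1099 over permuted, highest other 228.6) were the others. Divisions that mix genotypes hold genotype differences as spread within groups, and so call fewer genes. The result thus speaks only against libraries that do not differ by genotype. It cannot show that overlaps, chromosome shares or neighbouring pairs exceed what such long lists would give.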

How the results depend on the processing

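The run without WT replicate 1 and pll3 replicate 1, the tests without overlapping gene models and within expression level, the lists with accidental symbol matches and the families and lists between mutants without single libraries were chosen only after the data had been seen. Of 4300 values for 180 named genes in single comparisons, 4246 kept their direction and side of the threshold, 50 lost the call, 4 were lower in adjusted p and gained it, and 0 changed direction, by edgeR or the tool of the alternative. The rule for naming genes took called genes, many of them with all mutant libraries on the same side of WT. The lack of changed directions was thus largely set by that choice. The calls lost included MpPPO47, MpPPO10, MpH4c, MpMCM6, MpCDKA and MpCDKB in pll1, MpCupin96, MpCYP813B1, MpATXR6, MpCupin88 and Mp3g03850 in pll2, and MpPR1j, Mp4g15050 and the falling LEA genes in pll3. Of 238 list values against WT 217 kept the call, of 96 between mutants 90, of 372 family values 354, of 112 chromosome values 99, and of 102 neighbour values all 102. With a 2-fold minimum the gene counts were 951, 971 and 1332 against WT, 1059, 1304 and 993 between mutants, 224 for all 3 mutants and 330, 388 and 474 for the overlaps, and 13 chromosome tests passed. With only the groups compared, pll3 against WT gave 3170 calls. With an estimated correlation 0, 0 and 0 lists were called by camera in pll1, pll2 and pll3, and fry called 4 in pll2 and 9 in pll3. Leaving out single libraries gave 2199 to 5038 calls for pll1, 2801 to 4914 for pll2 and 4327 to 5303 for pll3 against WT, 3094 to 5836 for pll2 against pll1, 4807 to 6513 for pll3 against pll1 and 2794 to 4298 for pll3 against pll2. It gave 698 to 1295 genes common to the 3 mutants, overlaps of 994 to 1926, 1070 to 2150 and 1633 to 2533, 7 to 8, 1 to 4 and 4 to 5 lists, 7 to 13 chromosome tests (13 without pll2 replicate 1) and 6 neighbour tests each time. Fewer libraries were then tested, and other causes were not tested. Without both WT replicate 1 and pll3 replicate 1 the counts against WT were 4853, 4969 and 5109, and 1328 for all 3 mutants. DESeq2 called 4652, 4648 and 5808 genes against WT. Library totals in place of TMM moved the share of higher calls most in pll3 against pll1, from 51.4 to 44.2%. The majority in that comparison also turned without pll1 replicate 1 (2469 higher, 2530 lower), 2 (2517 and 2590) or 3 (2393 and 2414), and that in pll2 against WT without both WT replicate 1 and pll3 replicate 1 (2468 and 2501). The replicate number did not pair the samples, since correlations of deviations between libraries of the same number ran from −0.20 to 0.14 and 4 of 12 libraries correlated best with their own number. With the replicate block 3954, 3940 and 5191 genes were called against WT and 963 in all 3 mutants, and the terpene list in pll1 (0.0754 by camera) and chromosome 5 in pll2 (0.0785) were no longer called. Depth limited weakly expressed genes, since 3 counts stand for 0.0652 to 0.0709 CPM.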

Other observations

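The families in this part were defined and tested, with and without single libraries, and the genes without counts in a group were counted, only after the data had been seen.

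Families of genes with a common symbol stem were tested beside the lists, which hold many of the same genes, such as the PR, peroxidase, polyphenol oxidase and WRKY genes. Of 38 PR genes, 24 rose and 2 fell in pll1, 19 rose and 3 fell in pll2, and 27 rose and 3 fell in pll3 (camera adjusted p = 3.19e-07, 0.000887 and 1.27e-07). With an estimated correlation the camera adjusted p of the PR genes was 0.637, 0.693 and 0.427. Of 22 genes of polyketide and chalcone synthases, 12, 14 and 15 rose and 0, 1 and 1 fell (camera adjusted p = 0.000144, 3.53e-05 and 5.01e-06, and adjusted p = 0.636, 0.294 and 0.427 with an estimated correlation). Of 41 polyphenol oxidase genes, 18 rose and 2 fell in pll2 (camera adjusted p = 8.91e-05), and 31 rose and 2 fell in pll3 (1.27e-07), with adjusted p = 0.494 and 0.427 with an estimated correlation. Of 31 ABC transporters of the G class, 17 rose and 2 fell in pll2 (camera adjusted p = 0.00259), and 17 rose and 4 fell in pll3 (0.00438), with adjusted p = 0.294 and 0.427 with an estimated correlation. Of 45 dirigent genes, 25 rose and 5 fell in pll1 (camera adjusted p = 0.000236), and 20 rose and 5 fell in pll2 (0.00303), with adjusted p = 0.636 and 0.494 with an estimated correlation.

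In pll3 the WRKY factors, 13 genes, had 8 higher and 0 lower members (camera adjusted p = 0.00887, lost at 0.0579 without pll3 replicate 3), and the class III peroxidases, 137 genes, 61 higher and 14 lower (3.2e-05). With an estimated correlation the camera adjusted p was 0.711 and 0.427. Of the 55 LEA-like genes, 30 rose and 4 fell in pll1 (camera adjusted p = 2.25e-06), and 18 rose and 3 fell in pll2 (camera adjusted p = 0.00262). The camera adjusted p was 0.637 and 0.722 with an estimated correlation. In pll3 the family was not called, with 10 genes higher and 20 lower. WT replicate 1 stood apart in this family, with a median deviation of −1.14 against −0.02 and 0.03 in the other WT libraries and 0.56, 0.18 and 0.48 in pll2, and without it the camera adjusted p was 6.57e-06 in pll1 and 0.203 in pll2, where the call was lost. Of 11 genes of the pectin methylesterase-type family CE8, 5 fell and 0 rose in pll1 (camera adjusted p = 0.00764, and adjusted p = 0.636 with an estimated correlation). Over the 68 families, the lowest camera adjusted p with an estimated correlation was 0.294, so that no family call held in that form. MpPR1m and MpGH19.8, the latter of a chitinase-type family, were abundant genes that fell in pll2 and rose in pll3, at 113, 70.8, 46.3 and 253 CPM and at 179, 207, 97.2 and 346 CPM in WT, pll1, pll2 and pll3. MpR2R3-MYB1 lay at 16.6 CPM in WT and pll1, 7.04 CPM in pll2 and 5.75 CPM in pll3 (edgeR adjusted p = 0.99, 0.00095 and 0.00019). Of the sperm genes, MpDUO1 lay at 1.83 CPM in WT and 2.54, 1.59 and 1.11 CPM in the mutants, with an edgeR adjusted p of 0.033 in pll3.

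A few genes were present in one genotype and all but absent from another. With at most 3 counts over a group on one side and at least 1 CPM on the other, 3, 2 and 14 genes were off in pll1, pll2 and pll3, and 3, 4 and 4 were on in the mutant while off in WT. On chromosome 5, MpATXR6 (22275970 to 22279583) fell in pll1 and pll3 to 0.0591 and 0.108 CPM, and the near Mp5g20870 (start 22323711), with 2 counts in WT and 0 in pll2, was on in exactly these lines, at 6.5 and 4.97 CPM. On chromosome 4, Mp4g14850 was on in all 3 mutants and Mp4g15050 (start 17322929) was off in pll3. Like MpLEA-like9, Mp4g15050 was uneven in WT (0.767, 22.4 and 19.8 CPM) and highest in pll1 (62.3, 37.1 and 35 CPM). MpBHLH20 was also among the 14 genes off in pll3. For genes with these distributions, seedling pools that differed apart from genotype stay open, as given above. In pll3, Mp1g02420 and Mp1g02430, which start 2646704 and 2646826 bases along chromosome 1, had 0 counts against 3.31 and 1.96 CPM in WT and 16.5 and 9.03 CPM in pll1.

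Such genes raised the hypothesis that the mutant lines carry long chromosome segments of another parental line, whose sequence differences could set many of the calls. Called genes in either direction would then lie in long runs. Genes 20 places apart were both called 1072 times in pll1, 1069 times in pll2 and 1930 times in pll3, which is 1.02, 0.975 and 1.02 times the number after permutation (permutation p = 0.23, 0.88 and 0.104), while directly adjacent genes reached 1.21, 1.18 and 1.11 times. The lowest ratio, 0.975 in pll2 (SD of the permutations 0.022), argues against long segments, shorter than a chromosome, as the source of a large share of the calls in pll2. In pll1 and pll3 the ratios of 1.02 (SD 0.022 and 0.014) were not past the permutation test. How large a share the test would have found was not examined with planted segments. Calls were permuted within chromosomes, so segments that fill a chromosome would not be seen. Short segments, deletions or mapping differences at the single genes named above remain open, since no sequence was examined here.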
